A study of Drosophila melanogaster with 3 samples.

How the data were processed

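Gene expression in Drosophila melanogaster salivary glands after RNA interference (RNAi) against the gene sage was measured on 3 arrays with 2 dyes each. Per the labels, each array carried RNA of an RNAi sample beside RNA of a control sample, the 3 hybridizations used independent samples, and glands of 9 or 10 individuals went into each sample. The animals were kept at 25 °C on corn meal food that held bromophenol blue at 0.05%, and total RNA was amplified by in vitro transcription before labelling, per the labels' protocols. The RNAi sample was labelled with Cy3 on array No1 and with Cy5 on arrays No2 and No4, so No1 is the dye-swapped array. The sample titles carry the mark 20hr, whose reference point is not given in the sources used here.

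The deposited value table holds log2 ratios, 1 per spot, for 20000 spots per array. After 1 constant per array was taken off (0.06, 0.16 and 0.07 on the log2 scale for No1, No2 and No4), 100.0% of the values on each array were log2 of a ratio with 3 decimals, within 0.02 of the last decimal. Of the reciprocals, between 5.82% and 6.37% had 3 decimals within the same tolerance. The highest value of each array stood at a ratio of 100000, a ceiling that was treated here as no measurement. It occurred at 49, 34 and 53 spots of No1, No2 and No4, and a further 150, 164 and 257 spots were empty. The scanner software, the background correction and the way the authors set the constant are not given in the sources used here. Intensities were not used here, so the signal over background behind a spot is unknown, and the number of arrays limits the precision. The medians of the deposited columns were 0.02, -0.01 and 0.00 for No1, No2 and No4.

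The rounding shows that the authors' exported ratios were not inverted afterwards. If the export put the 635 nm channel (Cy5) over the 532 nm channel (Cy3) on every array, as 1 channel order for all arrays would, No1 holds control over RNAi and its sign has to be turned. Values are therefore given as RNAi over control with the sign of No1 turned. This differs from the rule fixed before the data were examined. That rule gave No1 the sign, as deposited or turned, with a positive correlation with the mean of No2 and No4 over all probes. Where the correlation lay within 0.05 of 0 under both signs, the rule turned No1. As deposited, the correlation was 0.0715 over 19478 probes, so the rule would have left No1 as deposited. The sign was turned after the values of the sage probe and these correlations had been seen, and the counts of probes, genes and lists that passed are given for No1 as deposited too. With that sign 0 probes and 0 genes passed an adjusted p of 0.05 in limma, with 1057 probes and 516 genes at an unadjusted p under 0.05. These are more than the 756 probes and 329 genes with No1 turned. With no change at all, 974 probes and 494 genes would have such a p. A further check, chosen after the data were seen, took the genes beyond 0.7 on the log2 scale in the same direction on both No2 and No4, between which no sign has to be set. Of these 27 genes, 25 lay on the same side on No1 turned, 17 of them beyond 0.7, and 0 lay beyond 0.7 in that direction on No1 as deposited. Of 48 genes beyond 0.5, 41 lay on the same side on No1 turned, and of 188 genes beyond 0.3, 110 did. Past the same cut in that direction on No1 lay 26 of the 48 and 69 of the 188 as turned, and 5 and 31 as deposited. Of the 47 higher genes beyond 0.3, 24 lay on the same side on No1 turned. The 27 genes include sage, seen before the turn, and GstD genes, which may share hybridisation and so may not count separately.

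Each array was centred on its median, and 19478 probes measured on all 3 arrays were tested with limma 3.58.1 in R 4.3.3: 1 coefficient per probe against 0, moderated variances (eBayes, 2 residual degrees of freedom and 5.22 prior ones) and Benjamini-Hochberg adjustment, with a threshold of 0.05. Standard errors are those of this fit, and SDs are over the 3 arrays. Gene names came from GEO's platform annotation of the probes: 10827 probes had 1 gene symbol, 227 had several and 8946 had none in it. Probes with several symbols were not named. Of the probes with 1 symbol, 10823 matched the reference gene table (assembly Release 6 plus ISO1 MT) by gene ID, with 0 symbols updated. The build behind the array is not given in the sources used here, so the reference table served only for names and for which genes neighbour each other. For values per gene, probes of a gene were averaged, 789 genes having 2 or more, and 9889 genes were tested in the same way (7.24 prior degrees of freedom). This test per gene was added after the data were examined as a count of changed genes.

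Before the data were examined, 28 gene lists were written from general knowledge of Drosophila genes, for salivary gland products and regulators, ecdysone response, cell death, autophagy, secretion, translation, energy metabolism, stress, immunity, detoxification and markers of other tissues. Shifts of lists with at least 4 measured genes were tested with limma's camera at a preset correlation of 0.01, Benjamini-Hochberg adjusted over the 28 lists. The test was repeated with the correlation estimated from the residuals, on ranks, and with fry. Camera compares a list with the other genes, so its direction can differ from the sign of a mean. The genes named are sage, the 10 higher and 10 lower probes with the largest mean among those that passed with 1 sign on all arrays, filled up to 5 per side by the moderated statistic where fewer passed, and up to 4 members per list. Genes named outside this rule were chosen after their values were seen. They are those called by the test per gene, glutathione S-transferase genes, verm, spz, Swip-1 and pairs of neighbouring genes. Further list members were also named so, among them Tm2, Mlc2, Prm and TpnC73F.

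Other settings were chosen before the data were examined: the other sign for No1, only No2 and No4, no centring, scale normalization, a dye term, probes on at least 2 arrays, leaving out the 10% most variable probes, robust eBayes, array weights, each array left out, other thresholds and the strongest probe per gene. Chosen after the data were seen were keeping ceiling values, testing only probes with 1 gene, and leaving out spots near background. Spots were taken as near background where the ratio was that of 2 whole numbers up to 15 on all 3 arrays. No intensities were used to test this. It held for 248 probes where 10.3 would be so if arrays were independent. It was picked from 18 definitions tried, under which the correlation of No1 as deposited with the others ran from -0.00336 to 0.0655 and lay within 0.05 of 0 under 17.

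The limma steps were tested on simulated data with 200 changed items. That many changed items loosen the Benjamini-Hochberg threshold. The shares called can therefore overstate what could be detected in the data, where few items passed. With variances drawn from the fitted prior, 84.0% of the probes and 96.0% of the genes changed by 1 on the log2 scale were called, against 0% and 24% of those changed by 0.5, and 3.45% and 1.24% of calls were false. With each item's observed variance, 32% of the probes and 80% of the genes changed by 0.5 were called, and 15.3% of the probe calls and 8.65% of the gene calls were false, above the 5% level the adjustment aims at. Camera on simulated independent genes gave 11 of 200 unshifted lists a p under 0.05. This does not test camera where the genes of a list vary together. In the data, the correlation estimated for the 8 lists that passed ran from -0.04 (muscle markers) to 0.59 (V-ATPase). It was 0.51 for heat shock and chaperones, 0.27 for the secretory pathway and 0.19 for folding in the endoplasmic reticulum, against the preset 0.01. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6.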

Results

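The data compare salivary glands after RNAi against sage with control glands, on 3 arrays of independent samples named No1, No2 and No4. The gene sage encodes a basic helix-loop-helix transcription factor of the salivary gland. The comparison asks which transcripts differ in these glands when sage is targeted. Measured spots numbered 19801 on No1, 19802 on No2 and 19690 on No4, with an SD of the log2 ratio of 0.33, 0.40 and 0.31 across spots. All ratios are RNAi over control, with the sign of the dye-swapped array No1 turned, a choice that departs from the rule fixed before the data were examined. The limma p-values per probe and per gene measure the spread between these 3 pairs of samples. Those of camera set the genes of a list against the other genes. At the preset correlation they do not measure how a list's mean varies between arrays. The permutation p-values compare genes with random draws of genes.

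With No1 turned, the targeted gene was lower in the RNAi samples on each array. That direction is likely rather than settled, since it assumes ratios of Cy5 over Cy3. No1 was turned after this probe had been seen, so its shared sign and p-value are no independent check of the turn. The deposited log2 ratio of the sage probe was -2.61 on No2 and -2.66 on No4, where the RNAi sample carried Cy5, and 2.55 on No1, where it carried Cy3. After turning No1 and centring, sage fell by 2.59 on the log2 scale (SD 0.07, standard error 0.11, n = 3), which is 6.04-fold lower (limma adjusted p = 0.00105 over all probes). With the sign of No1 as deposited the mean was -0.91 and the adjusted p 0.878.

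Few other transcripts passed. Of changes of 0.5 on the log2 scale, simulated with variances from the fitted prior or as observed, the test called 0% or 32% of probes and 24% or 80% of genes. Per probe, 5 passed in limma, 2 higher and 3 lower. Beside sage, the glue protein gene Sgs1 fell by 1.43 on the log2 scale (SD 0.20, n = 3, 2.69-fold lower, limma adjusted p = 0.0389). Sgs5bis, a gene related to the glue gene Sgs5, fell by 1.62 (SD 0.22, 3.08-fold lower, limma adjusted p = 0.0340). CG17362 rose by 1.93 (SD 0.39, 3.82-fold higher, limma adjusted p = 0.0340). The other higher probe, number 12177, has no gene name in the annotation used. Its mean was 2.82 (SD 0.79, limma adjusted p = 0.0449), and its ratios were those of small whole numbers on all 3 arrays, which was taken here, without intensities to test it, as a mark of spots near background. Those next by the moderated statistic under the naming rule did not pass: probe 12182 at 1.78, Hsp68 at 1.61 and Hsp22 at 0.97 on the higher side, and CG17134 and probe 14249, both at -1.24, on the lower side. At an unadjusted p under 0.05 there were 756 probes, fewer than the 974 that no change would give. The count of 5 rose to 26 without No1, 8 without No2 and 9 without No4, and Sgs1 missed the threshold without No1 (adjusted p = 0.0521) and without No4 (0.0786), as probe 12177 did without No2 (0.0859). It was 0 with No1 as deposited, 10 without centring (2 higher and 8 lower) and 2 after scale normalization (0 higher and 2 lower). Scale normalization lost CG17362 (limma adjusted p = 0.0981), Sgs1 (0.0987) and probe 12177 (0.105). With probes on at least 2 arrays only sage passed, with CG17362, Sgs1 and Sgs5bis at an adjusted p of 0.0795. With ceiling values kept only sage passed too, with these genes at 0.158.

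With probes averaged per gene and only named genes tested, 21 of 9889 genes passed in limma, 5 higher and 16 lower. Of the 21, 4 also passed by their probe in the test per probe: sage, Sgs1, Sgs5bis and CG17362. Except for CG8087, each of the 21 was read by 1 probe, so averaging left its values unchanged. The added calls therefore depend on the set of items tested and on the fitted prior. The higher genes were CG17362, Hsp68, which encodes an inducible heat shock protein (1.61, SD 0.55, 3.05-fold, adjusted p = 0.0110), the small heat shock gene Hsp22 (0.97, SD 0.25, 1.96-fold, adjusted p = 0.0204), CG8087 (0.92, SD 0.33, adjusted p = 0.0419) and Sodh2, a sorbitol dehydrogenase gene (0.85, SD 0.30, adjusted p = 0.0499), n = 3 throughout. The lower genes were sage, Sgs1, Sgs5bis, 6 glutathione S-transferase genes of the GstD group, CG17134 (-1.24, SD 0.16, adjusted p = 0.00256), CG13946, CG4174, CG12506, regucalcin, CG4404 and CG13947. The last 6 ranged from -0.88 to -0.69. Each of the 21 genes had the same sign on all 3 arrays. Without No1, 7 of the 21 remained past the threshold, namely sage, Sgs1, Sgs5bis, CG17134, GstD1, Hsp68 and CG17362, and 8 genes passed in all. The other 14 then had limma adjusted p-values from 0.0524 to 0.397. Without No2 the count was 38 (12 higher and 26 lower) with all 21 among them. Without No4 it was 36 with 19 of the 21 among them, CG13947 (adjusted p = 0.138) and CG4404 (0.0619) being lost, and the balance turned to 21 higher and 15 lower. With a dye term it was 13, 5 higher and 8 lower, with 11 of the 21 among them. Sodh2 (limma adjusted p = 0.0511) was among the calls lost. After scale normalization it was 14, 2 higher and 12 lower, all among the 21. The calls lost were Hsp22 (adjusted p = 0.0508), CG8087 (0.0889), Sodh2 (0.0927), CG4174, CG12506, CG4404 and CG13947. It was 0 genes with No1 as deposited. At an unadjusted p under 0.05 there were 329 genes with No1 turned and 516 as deposited, where no change would give 494.

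**Figure D1:**
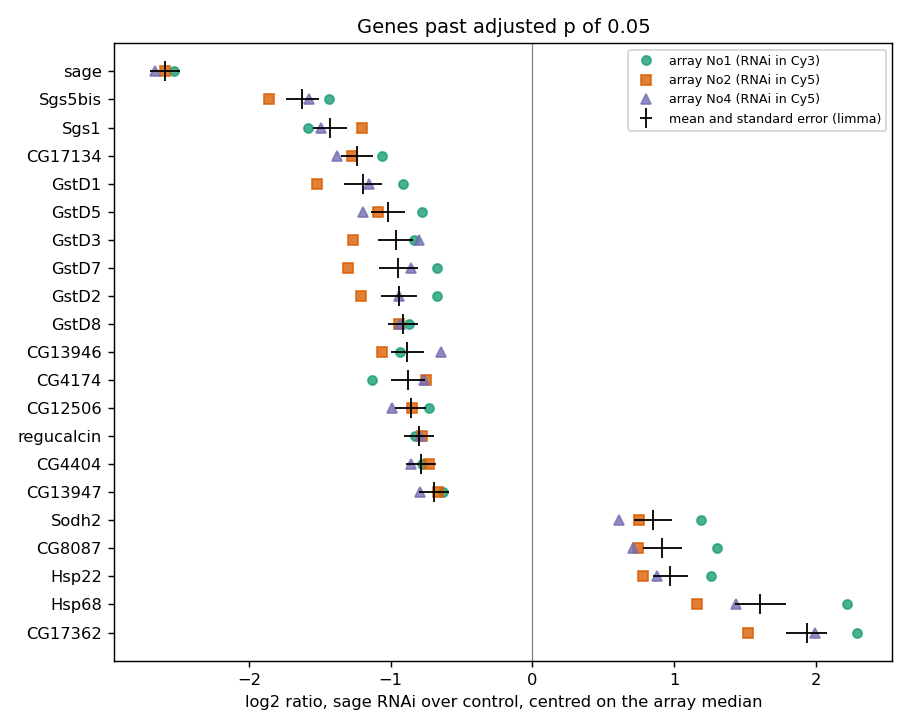
Log2 ratio of sage RNAi over control (x axis) for the 21 genes that passed in the test per gene, 1 per line, with a symbol for each of the 3 arrays and a bar for the mean with its standard error. For sage the arrays lie between -2.66 and -2.53, and for Hsp68 between 1.16 and 2.22.

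Genes of the GstD group, enzymes that join glutathione to foreign and oxidised compounds, made up 6 of the 16 lower genes. Of 11 measured GstD genes, 6 fell, 0 rose and 5 did not pass in the test per gene, which was added after the data were examined. Each of the 6 was read by 1 probe and did not pass in the test per probe. There the limma adjusted p-values ran from 0.0788 (GstD1) to 0.178 (GstD7). The group was picked out after the values were seen and was not tested for enrichment. GstD1 fell by 1.20 (SD 0.31, n = 3, 2.29-fold lower, limma adjusted p = 0.0110), GstD5 by 1.02 (SD 0.22, adjusted p = 0.0119), GstD3 by 0.97, GstD7 by 0.95, GstD2 by 0.94 and GstD8 by 0.91. GstD10 was at -0.69 (adjusted p = 0.182) and GstD4 at -0.39 (0.736), while GstD6, GstD11 and GstD9 lay between -0.15 and -0.10. Of 16 glutathione S-transferase genes of other classes 0 passed in limma and 3 had an unadjusted p under 0.05, GstE3 lower at -0.39 and GstO2 and GstO3 higher at 0.27 and 0.28. The GstD genes belong to the list of detoxification genes. Of its 104 measured genes, 6 fell and 0 rose over all genes, all of them GstD, and 7 fell when adjusted over the list alone, GstD10 being the added one. The list as a whole, with a mean of -0.07, did not pass in camera (adjusted p = 0.0915). Without No1, GstD1 alone of the 6 still passed over all genes (adjusted p = 0.0405), and the other 5 lay between 0.0524 (GstD5) and 0.156 (GstD3). The log2 values of these 5 were then from -1.14 (GstD5) to -0.94 (GstD8). With a dye term, which leaves 1 residual degree of freedom, GstD1 and GstD5 passed, and GstD2, GstD3, GstD7 and GstD8 had adjusted p-values from 0.0537 to 0.118 at log2 values from -0.93 to -0.87.

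**Figure D2:**
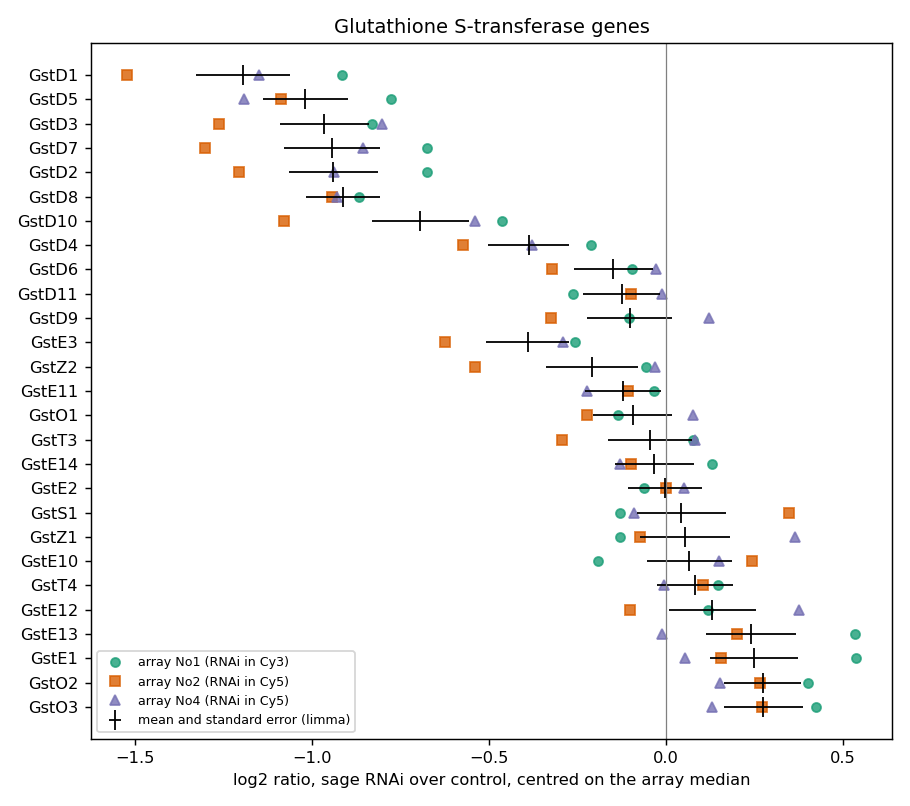
Log2 ratio of sage RNAi over control (x axis) for 11 GstD genes (upper lines) and 16 glutathione S-transferase genes of other classes, with a symbol per array and a bar for the mean with its standard error. The 6 lowest GstD means lie between -1.20 and -0.91, and GstE3 is the lowest of the other classes at -0.39.

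Glue protein genes, whose products the larval salivary gland secretes to fix the pupal case, were lower as a list. The mean over 5 measured genes was -0.70 (array means -0.65, -0.88 and -0.57 for No1, No2 and No4, camera adjusted p = 2.36e-08). The call was lost with an estimated correlation (adjusted p = 0.556 with an estimated correlation) and on ranks (adjusted p = 0.130). Of these, 2 fell over all genes, Sgs1 and Sgs5bis, and 3 fell adjusted over the list alone, the added one being ng3 at -0.45 (SD 0.28, adjusted p = 0.0101 over the list and 0.618 over all genes). Sgs5 was at -0.02 and Eig71Ee at 0.02. Among 5 salivary gland transcription factor genes only sage fell, over all genes and adjusted over the list alone, with eyg at 0.23, fkh at 0.01, Scr at -0.05 and hkb at -0.05. That list did not pass (mean -0.49, camera adjusted p = 0.0725), nor did 5 genes of salivary gland secretory enzymes (mean 0.09, adjusted p = 0.240), of which Pgant9 was the highest at 0.27 (SD 0.71).

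Heat shock and chaperone genes rose as a list, most on No1. The mean over 20 genes was 0.29 (camera adjusted p = 3.57e-11), with array means of 0.59, 0.25 and 0.02 for No1, No2 and No4. With an estimated correlation the call was lost (adjusted p = 0.563 with an estimated correlation). Over all genes 2 rose, 0 fell and 18 did not pass, and adjusted over the list alone 5 rose and 1 fell. The 5 were Hsp68, Hsp22, the small heat shock gene Hsp27 (0.47, SD 0.26), DnaJ-1, a co-chaperone gene (0.36, SD 0.17), and Hsc70-5, a mitochondrial chaperone gene (0.54, SD 0.53). The lower one was CG4456, which the list held as Hsp67Bb (-0.74, SD 0.29, adjusted p = 0.00177 over the list and 0.0897 over all genes). Without No1 the list's mean was 0.13, and it still passed (adjusted p = 0.00228). Lists that did not pass were also highest on No1: cytosolic ribosomal proteins had array means of 0.35, -0.18 and -0.04, the proteasome 0.27, -0.04 and -0.18, and oxidative phosphorylation 0.23, -0.25 and -0.11. Read as Cy5 over Cy3, with No1 turned back, each of these lists lay below 0 on every array, as a dye effect would also give. With 1 swapped array, that cannot be told apart from variation of No1.

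Genes for folding in the endoplasmic reticulum rose as a list of 18, with a mean of 0.19 (array means 0.41, 0.20 and -0.04, camera adjusted p = 5.72e-06). The call was lost with an estimated correlation (adjusted p = 0.563 with an estimated correlation). Over all genes 0 passed in limma, with 6 higher at an unadjusted p under 0.05, and 1 rose adjusted over the list alone, Hsc70-3, the Hsp70 chaperone of that compartment (0.66, SD 0.37, adjusted p = 0.0228 over the list). Pdi, a disulfide isomerase gene, was at 0.48 (SD 0.36), and wbl at 0.29 (SD 0.04). Genes of the V-ATPase, the proton pump of acidic organelles, rose as a list of 16 (mean 0.15, array means 0.40, 0.22 and -0.19, camera adjusted p = 9.32e-05, but adjusted p = 0.783 with an estimated correlation), with ATP6AP2 at 0.28 (SD 0.07), Vha26 at 0.37 (SD 0.39) and VhaM9.7-b at -0.28 (SD 0.17). The secretory pathway list of 25 genes also rose (mean 0.06, array means 0.29, 0.00 and -0.12, camera adjusted p = 0.0355, but adjusted p = 0.853 with an estimated correlation and 0.0740 on ranks), with the signal peptidase genes Spase25 at 0.42 (SD 0.19) and Spase12 at -0.44 (SD 0.60). The secretory call was also lost after scale normalization (camera adjusted p = 0.0683) and with array weights (0.0831). In the V-ATPase and secretory lists 0 genes passed over all genes or adjusted over the list alone, and 4 (3 higher and 1 lower) and 3 (2 higher and 1 lower) had an unadjusted p under 0.05. The first of these 3 calls was lost without No1, and the other two without No1 and also without No2. The ribosomal, proteasome and oxidative phosphorylation lists were likewise highest on No1. Without No1 the means, in the order given, were 0.08 (adjusted p = 0.0536), 0.02 (0.302) and -0.06 (0.951), without No2 the V-ATPase mean was 0.11 (0.0891) and the secretory mean 0.08 (0.0891), and without No4 the means were 0.31, 0.31 and 0.14 with adjusted p-values of 5.72e-11, 4.50e-12 and 1.47e-05.

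**Figure D3:**
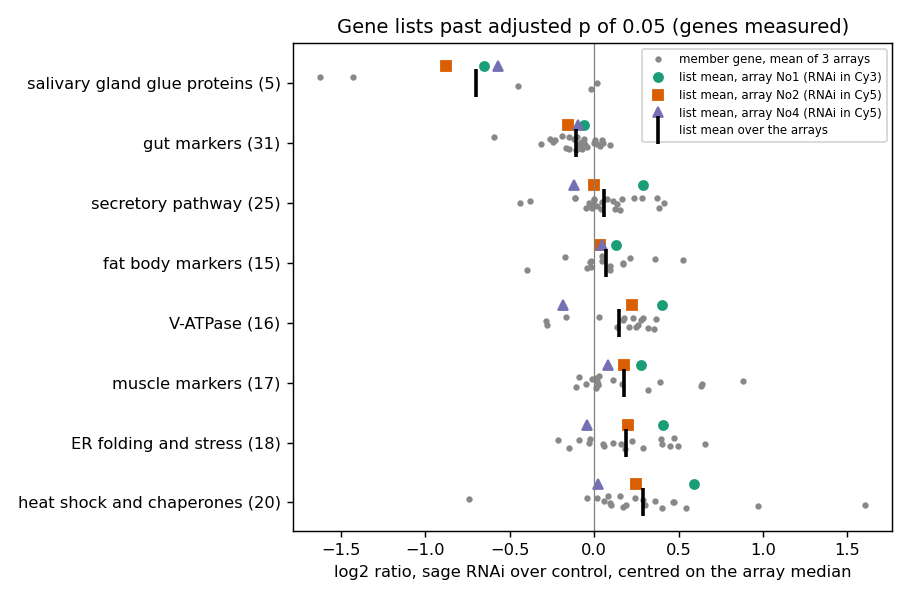
Log2 ratio of sage RNAi over control (x axis) for the 8 gene lists that passed in camera, with the number of genes measured in brackets, grey points for the member genes, a symbol for the list mean on each array and a black bar for the mean over the arrays. The glue list lies at -0.70, and the V-ATPase list lies at 0.40 on No1 and at -0.19 on No4.

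Markers of tissues other than the salivary gland were also compared. Muscle markers rose as a list of 17 (mean 0.18, median 0.02, array means 0.28, 0.18 and 0.08, camera adjusted p = 9.24e-05, but adjusted p = 0.556 with an estimated correlation). Over all genes 0 passed in limma, and adjusted over the list alone 4 rose: the actin genes Act79B (0.64, SD 0.29) and Act88F (0.63, SD 0.35), the myosin light chain gene Mlc1 (0.88, SD 0.62) and flw, a protein phosphatase gene (0.39, SD 0.14). At an unadjusted p under 0.05 the count was also 4. Of the 17 markers, 13 lay above 0 and 4 below. Some other genes of muscle filaments stayed near 0, with Tm2 at -0.09, Mlc2 at -0.05, Prm at 0.02 and TpnC73F at 0.01. Gut markers fell as a list of 31 (mean -0.10, array means -0.06, -0.16 and -0.10, camera adjusted p = 0.00281, but adjusted p = 0.556 with an estimated correlation), with the amylase genes Amy-d at -0.32 (SD 0.12) and Amy-p at -0.26 (SD 0.14). Fat body markers rose as a list of 15 (mean 0.07, array means 0.13, 0.04 and 0.04, camera adjusted p = 0.0363, but adjusted p = 0.563 with an estimated correlation and 0.119 on ranks), with the larval serum protein gene Lsp2 at 0.36 (SD 0.17). In the gut and fat body lists 0 genes passed in limma over all genes or adjusted over the list alone, with 3 and 2 at an unadjusted p under 0.05. The gut list did not pass without No4 (adjusted p = 0.0612), and the fat body list did not pass without No1 (mean 0.04, adjusted p = 0.161), without No2 (0.132) or without No4 (0.0556). With the strongest probe per gene the fat body list did not pass either (camera adjusted p = 0.0642).

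The other 18 lists had means from -0.10 to 0.09, camera adjusted p-values from 0.0725 to 0.899 and 0 genes past the limma threshold over all genes or adjusted over the list alone, with 18 of their 475 members at an unadjusted p under 0.05. This group includes the salivary gland secretory enzymes above. Antimicrobial peptide and immune genes had a mean of -0.10, cytosolic ribosomal proteins 0.04, mitochondrial ribosomal proteins -0.02, the proteasome 0.02, autophagy 0.01 and lysosome and cathepsin genes -0.05. Cuticle and epidermis genes were at -0.04, oxidative phosphorylation at -0.04, cell cycle and DNA replication genes at -0.03, haemocyte markers at -0.04, nervous system markers at 0.04 and mucins at -0.03. Regulators of the ecdysone response, the steroid hormone pathway of moulting, had a mean of 0.00, with EcR at 0.24 (SD 0.37) and svp at -0.26 (SD 0.17). Late puff genes of the 71E cluster were at -0.03. Mean and median differed in sign for the ecdysone-induced effectors (0.03 and -0.04) and for glycolysis (-0.07 and 0.01). Cell death genes had a mean of -0.01 and a median of 0.00, although camera set them above the other genes, and Dredd, a caspase gene, was at -0.26 (SD 0.30). Of the 28 lists, 8 passed with the preset correlation of 0.01, 6 higher and 2 lower. The balance turned to 2 higher and 5 lower without No1, with 4 of the 8 among them, and to 4 higher and 5 lower without No2, with 5 of the 8. Without No4 it was 8 higher and 2 lower, with 6 of the 8. With an estimated correlation 0 passed, with 2 at an unadjusted p under 0.05, and fry called 0, with 3 at an unadjusted p under 0.05. With No1 as deposited 3 lists passed, all lower and 0 of them among the 8, and after scale normalization the split was 5 higher and 3 lower. A dye term gave 11 lists, 8 higher and 3 lower, with all of the 8 among them.

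Across all probes the arrays shared little. The Pearson correlation over 19478 probes, which are not independent replicates, was -0.04 between No1 turned and No2, -0.07 between No1 turned and No4, and 0.09 between No2 and No4, and the Spearman correlations were -0.08, -0.10 and -0.02. The median SD of a probe over the arrays was 0.20 on the log2 scale. With No1 as deposited, its correlation with the mean of the other 2 arrays was 0.07 over all probes and -0.03 over the 10807 probes that name 1 gene.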

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

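The tests per gene, on probes naming 1 gene, without spots near background and with ceiling values kept were chosen after the data were seen, and the causes of the changes below were not tested unless stated. Sage stayed past the threshold at -2.65 to -2.56 in every setting but 1: with No1 as deposited it was -0.91. The main count of 5 probes became 0 with No1 as deposited, 26 on No2 and No4 alone, 10 without centring, 2 after scale normalization, 15 with a dye term, 1 for probes on at least 2 arrays, 16 with robust eBayes, 18 with array weights, 22 without spots near background, 24 on probes naming 1 gene, 1 with ceiling values kept, 21 at an adjusted p under 0.1 and 21 with probes averaged per gene. It was 227 without the 10% most variable probes, a selection on the residual SD that itself lowers the variances tested. Leaving out 1 array gave 8 to 26 probes, 26 of them without No1. Per gene, the count of 21 became 0 with No1 as deposited, 8 on No2 and No4 alone, 13 with a dye term, and 8 (without No1) to 38 (without No2) with 1 array left out, No4 giving 36.

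Of the lists, 3 passed with No1 as deposited, 11 with a dye term, 5 on ranks, 0 with an estimated correlation and 0 by fry. With No1 as deposited the mean turned to -0.12 for V-ATPase, -0.14 for the secretory pathway, -0.083 for folding in the endoplasmic reticulum, -0.11 for heat shock, -0.016 for fat body and -0.0072 for muscle, as turning 1 of 3 arrays must where No1 carries most of the shift. The secretory mean was -0.061 on No2 and No4 alone and -0.061 to 0.14 with 1 array left out. The correlation of No1 as deposited with the others, 0.0715, became 0.0279 without spots near background, -0.0266 on probes naming 1 gene and -0.0260 with both limits. Signal over background is unknown for every spot, which limits all of these values.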

Other observations

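The tests of the GstD genes, of array No1, of the muscle markers and of the sign patterns for probes and genes were chosen after the results were seen, and those of neighbouring genes and of the sign patterns for lists before. Outside the lists, verm, which encodes a chitin-binding protein, was read by 5 probes. Their average was -0.68 (SD 0.07, n = 3), just short of the limma threshold (adjusted p = 0.0508 over all genes). Of the 5 probes, 4 had means from -1.23 to -0.59, and probe 10271 was at 0.10. In all, 9 genes had an adjusted p from 0.05 to 0.1, among them spz, which encodes a Toll ligand, at 0.72 and Swip-1 at -0.82.

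The lower genes often lay side by side on the chromosomes. Among the 50 lowest genes by the moderated statistic there were 6 adjacent pairs, where 10000 random draws gave 0.26 on average (permutation p = 0.0001, the smallest these draws can give). The pairs were GstD1 with GstD2, GstD2 with GstD3, GstD7 with GstD8, CG12506 with CG13946, CG13946 with CG13947, and CG16713 with IM33. Without the GstD genes, 3 pairs remained against 0.252 by chance (permutation p = 0.0015), so the pairs were not all of GstD genes. CG12506, CG13946 and CG13947 form 1 run, so their pairs do not count separately. The 50 highest genes held 1 pair, against 0.25 by chance (permutation p = 0.225). Whether the remaining neighbours are related in sequence and share hybridisation was not tested.

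The fall of the GstD genes, which passed only in the test per gene, was weighed against 2 technical explanations. A dye effect alone would keep the sign of Cy5 over Cy3 on every array. Over the 7 GstD genes below -0.5 on both No2 and No4, picked without No1, the median was 0.778 as Cy5 over Cy3 on No1, against -1.21 on No2 and -0.93 on No4. The standard error of the mean over these genes on No1 was 0.06. It treats related genes on 1 array as replicates and does not measure error between arrays. If No1 does run Cy5 over Cy3, that argues against the dye as the whole source, though the group was noticed in a fit that included No1. A dye part, taken from the difference between No1 and the mean of the others, was -0.21 to -0.03. The RNAi part had a median of -0.90. With 1 swapped array, such a dye part cannot be told apart from variation of No1. Hybridisation shared between these related genes could spread a fall of 1 or a few of them to the others. Against this, 3 of the 11, GstD6, GstD9 and GstD11, lay above -0.2, but without probe sequences it cannot be told apart from a fall of each gene. A response of the GstD genes to sage RNAi stays open as a hypothesis.

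Array No1 as deposited correlated at 0.0715 with the mean of the other arrays, although 25 of the 27 genes beyond 0.7 on No2 and No4, sage among them, ran the opposite way there. Without the 248 probes taken as near background the correlation fell to 0.0279 (standard error 0.00717 for independent probes), which is consistent with these probes as the source of part of it. Their SD across probes within an array, averaged over the deposited arrays, was 1.21 on the log2 scale, against 0.275 for the others. Of the 248, 242 do not name 1 gene. That they lie near background rests on their ratios alone. What the rest of the correlation comes from was not tested, and since the definition of these spots was chosen after the data were seen, the test is open to that choice.

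Muscle tissue in the dissected RNAi samples may account for the higher muscle list, and it would raise its abundant transcripts alike. The median over the 17 markers was 0.0245, with a bootstrap interval from 0.01 to 0.32 that reaches the 0.3 set as the bound. Act79B, Act88F and Mlc1 were high while Tm2, Mlc2, Prm and TpnC73F, picked after their values were seen, stayed near 0. Of the 17 markers, 13 lay above 0 and 4 below. Of the 17 markers, 0 were on another list, and how many the gland itself expresses is unknown. With no intensities, a marker near 0 may be too dim to show a small share of muscle, so muscle tissue and a change in a few actin and myosin genes cannot be told apart. Of the other tissue lists, fat body also passed (0.07, but adjusted p = 0.563 with an estimated correlation, 0.119 on ranks and 0.0556 to 0.161 with 1 array left out). Gut markers passed as lower (-0.10, camera adjusted p = 0.00281, but 0.556 with an estimated correlation). Haemocyte markers were at -0.04.

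With 3 arrays there are 4 patterns of signs, too few for a share under 0.05. For probes, 1 of the 4 patterns, the one used, gave as many as 5, and the highest other count was 0. For genes, 1 of the 4 gave as many as 21, and the highest other count was 0. At an unadjusted p under 0.05 in limma the order differed, and the pattern used gave the fewest, 756 probes and 329 genes. The counts were 1057 and 516 with No1 as deposited, 794 and 542 with No2 turned, and 932 and 633 with No4 turned. For lists, 2 of the 4 gave as many as 8, and the highest other count was 9, with No4 turned.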
